A study of Homo sapiens with 6 samples.

How the data were processed

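Poly(A)-selected RNA of 2 human cell cultures was sequenced in 3 libraries each, 6 libraries in all. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made from 1 µg of total RNA with a directional NEBNext kit after poly(A) selection. The first group is T47D, a breast cancer line described in the labels as ER-positive. The other is T47D-TR, a tamoxifen-resistant subline derived from it and kept in 1 µM 4-hydroxytamoxifen, the active metabolite of tamoxifen. Both were grown in DMEM with 10% fetal bovine serum. The subline and the presence of the drug therefore changed together, and no sample separates them. Libraries were assigned to groups by their titles and source names. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

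Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to GRCh38 and compared with DESeq, whose version is not given in the sources used here. The counting tool, its strand setting and the gene annotation are not given in the sources used here. The deposited table has 20503 genes and holds whole-number read counts per gene and library, although its name says FPKM. The authors also deposited a mean per group on a normalized signal scale, which equals the mean of the counts after division by a size factor per library. Their fold change is deposited as a linear ratio of these means. The authors' log2 fold change is deposited beside it and is set to 20 in size where one group is at 0. The authors' p-value and false discovery rate stand in the same table, and the latter equals a Benjamini-Hochberg adjustment over all genes. The size factors implied by the authors' means were 1.006 to 1.011 times median-of-ratios factors computed from the counts. No column of per-sample values was left unused.

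Before the data were examined, the groups, tests, gene lists, rule for named genes and most alternatives were fixed. That plan assumed FPKM and a limma test on the log scale, and it stated that edgeR's quasi-likelihood test with filterByExpr would be used if the table held counts. This second form is the one reported. Counts were scaled with TMM, genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and glmQLFit and glmQLFTest compared T47D-TR with T47D. A gene is called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. Levels are CPM, counts scaled by TMM-adjusted library sizes, given as mean ± SD over the 3 libraries of a group. Log2 fold changes are T47D-TR over T47D from edgeR. Their SE comes from the spread between libraries of log2 CPM with a prior count of 2. The prior count narrows that spread where counts are low, so the SE is too small for genes with few counts in a group. Correlations and principal components used log2 CPM with a prior count of 2. Pairs of libraries were compared with a chi-square over genes with at least 20 counts in the pair.

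Of 43 gene lists fixed beforehand, the 41 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares the members of a list with all other tested genes. Member counts cover tested genes, so members missing from the table or removed by the filter are left out. For example, 16 of 25 fixed members were tested for luminal identity and 28 of 48 for drug metabolism and efflux, but all 25 for cholesterol biosynthesis. The named genes were ESR1, PGR, GREB1 and TFF1, the 10 largest changes in each direction among called genes of at least 2-fold with groups that did not overlap, and from each list up to 2 called members at each end. This rule took 175 genes. PGR and TFF1 were not analysed here. Some results are not reported here. Genes at 0 in one group are given as a lower bound against a floor of 3 counts over the group, and those with 1 to 3 counts as a ratio with a 95% interval from the exact (Clopper-Pearson) binomial interval of the counts. These intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Gene positions come from a RefSeq table for GRCh38.p14, in which 18021 genes were found by identifier and 1095 by symbol, while 1387 were not placed.

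For regional shifts, tested genes were ordered along the chromosomes and the median log2 fold change of blocks of 40 genes was compared with 1000 shuffled gene orders, at a z threshold of 4, which was set ahead of the real run but is not part of the written prediction. The procedures were tested on simulated data. In 15710 genes simulated for this comparison, edgeR recovered 48% of genes changed 1.25-fold, 62% at 1.5-fold, 92% at 2-fold and 94% at 4-fold, with 7 false calls among 155. Camera called 0 of 42 lists in a simulation without change, where edgeR called 0 genes, and found the 1 list that was lowered by 1.25-fold. That simulation draws genes independently of each other, and in mixed splits of the real libraries, where edgeR called 0 genes (42 to 128 at an unadjusted p under 0.05), camera with the preset correlation called 8 to 17 lists. Those splits keep part of the difference between the cultures, so these list calls are not a rate of false calls. The regional procedure called 17 of 37 blocks shifted by 0.5 on the log2 scale and 37 of 37 shifted by 1.0, with 0 other blocks.

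Alternatives were DESeq2, median-of-ratios factors, library size alone, no filter, no trend, a robust fit, a replicate block, leaving out each library, and camera with an estimated correlation or on ranks, and fry. Chosen after seeing the data were limma on log2(CPM + 1), log2(CPM + 0.1) and log2(CPM + 0.01), a mean CPM of at least 5, voom with quantile normalization, and a fit without the mitochondrially encoded genes. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.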

Results

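The transcriptomes of T47D cells and of the tamoxifen-resistant subline T47D-TR were profiled in 3 libraries each, to find the genes whose expression separates the resistant subline from its parent. The libraries labelled T47D held 18315735, 19305594 and 18495072 counts, and those labelled T47D-TR held 19491724, 19867230 and 17199315. At this depth 3 counts correspond to 0.153 to 0.178 CPM in a single library. Over 15961 tested genes, Pearson's r of log2 CPM was 0.990 to 0.994 between libraries of one group and 0.942 to 0.947 between groups, and the first principal component held 84.7% of the variance. These correlations are across genes, which are not independent replicates. The biological coefficient of variation was 0.0272 in T47D and 0.0799 in T47D-TR. T47D-TR replicate 3 stood apart from its group, with a chi-square per gene of 8.36 and 9.58 against the other T47D-TR libraries, which differed from each other by 2.79. The T47D pairs lay at 1.83 to 2.24. This chi-square treats reads as independent molecules and served to look for a library deposited more than once, of which no pair gave a sign.

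ESR1, which encodes oestrogen receptor alpha, the target of tamoxifen, was close to the limit of detection in both groups. The gene (chromosome 6, 151656672 to 152129619, GRCh38) had 3, 0 and 2 counts in the libraries labelled T47D and 2, 4 and 3 in those labelled T47D-TR, at most 0.204 CPM, so no fold is given. GREB1, an oestrogen receptor target, stood at 5.53 ± 0.146 CPM in T47D and 7.42 ± 0.809 in T47D-TR (log2 fold change 0.42 ± 0.09, edgeR adjusted p = 0.011), and with voom and quantile normalization the call ended at 0.19 and limma adjusted p = 0.189. Of the luminal transcription factor genes, FOXA1 rose from 5.64 ± 0.5 to 10.7 ± 1.05 CPM and GATA3 fell from 1.23 ± 0.14 to 0.625 ± 0.0774 CPM (log2 fold change -0.97, edgeR adjusted p = 0.0093), a call that DESeq2 did not make (adjusted p = 0.0607). Of 41 other listed luminal and epithelial adhesion genes, 11 lay under 1 CPM and 21 under 10 CPM in T47D. The 34 tested members of both lists had medians of 12.5 to 14.5 CPM in the T47D libraries, under the 18.3 CPM of all tested genes, and of 23.4 to 25.6 CPM in the T47D-TR libraries, above their 19.6 to 19.8 CPM. All 41 had medians of 7.98 to 9.92 CPM in T47D and 10.4 to 11.9 CPM in T47D-TR, above the 7.54 to 7.57 and 8.66 to 8.76 CPM of all genes in the table. The deposited table held 19 of the 25 luminal members, ESR1 included, and 23 of the 25 adhesion members. Each gene in it had at least 1 count, so members missing from it may have had none, and they are left out of these medians. Chosen after their values were seen, genes at high levels in T47D included VIM, which encodes the intermediate filament vimentin (770 ± 10.9 CPM), the adhesion receptor gene CD44 (488 CPM), the caveolin gene CAV1 (319 CPM), EGFR (140 ± 7.39 CPM) and the simple epithelial keratin genes KRT8 (1338 CPM) and KRT18 (683 CPM), while CDH1, which encodes E-cadherin, had 2.12 ± 0.742 CPM.

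**Figure D1:**
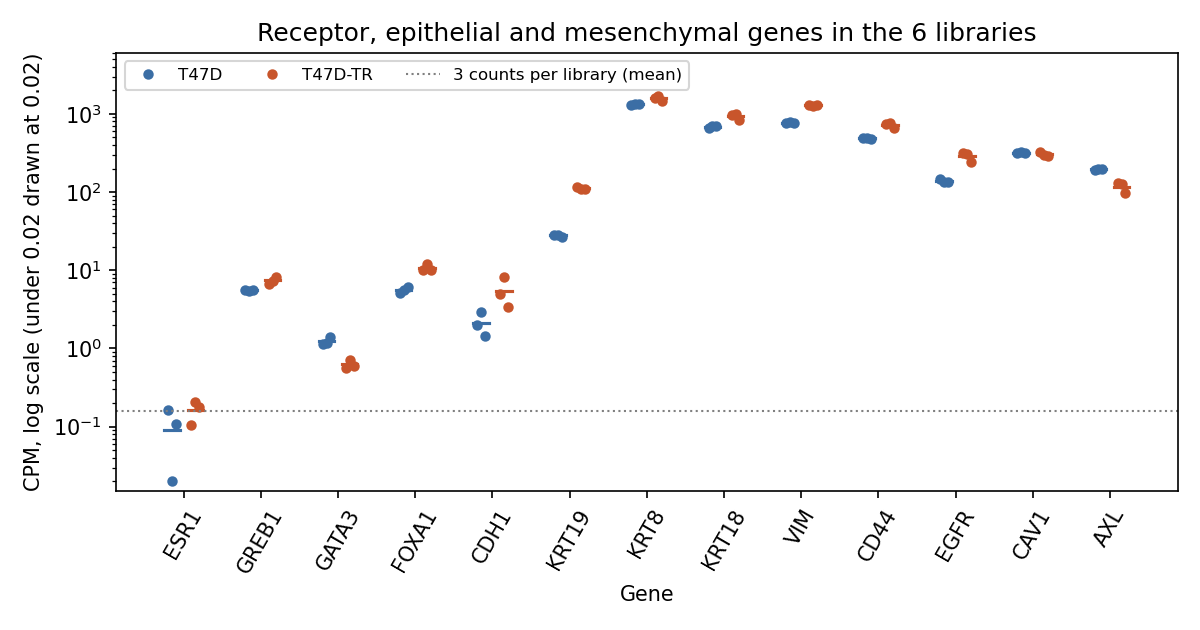
CPM on a log scale for 13 genes in each of the 6 libraries, with T47D in blue and T47D-TR in orange, short lines for group means and a dotted line for 3 counts per library. ESR1 lies around that line at 0 to 0.204 CPM in both groups, while VIM lies at 770 CPM in T47D and 1297 CPM in T47D-TR.

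Most tested genes differed between the cultures. edgeR called 10053 of 15961 genes (63.0%), of which 5186 were higher and 4867 lower in T47D-TR, with a median size of change of 0.52 on the log2 scale. At least 2-fold, 1617 genes were higher and 618 lower, so that 72.3% of these and 51.6% of all calls were higher. Quantile normalization with voom moved the log2 fold changes of single tested genes by a median of -0.11. With it 61.2% of the 2-fold calls and 43.0% of all calls were higher, so small changes are relative to the TMM scaling. The 3 libraries of one group lay entirely above or below the other 3 for 9826 of the called genes and for 68.3% of tested genes, against 10% by chance. It did so for each tested gene taken by the naming rule too, which is partly set by that rule. Of 41 gene lists, camera called 16 higher and 4 lower. It called 8 to 17 in mixed splits of the same libraries, which keep part of the difference between the cultures. With an estimated correlation 0 lists were called by camera (smallest adjusted p = 0.0879; 7 lists at an unadjusted p under 0.05), while camera on ranks called 14 higher and 4 lower and fry 28 and 5. Member counts adjusted over the list alone equalled those over all genes except where given.

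Genes induced by MAPK signalling, the growth-factor kinase cascade, rose together in T47D-TR. Of 19 tested members 16 rose, 1 fell and 2 were not called, with a median log2 fold change of 1.60 (camera adjusted p = 1.87e-12, and adjusted p = 0.334 with an estimated correlation). EGR1, an immediate-early transcription factor gene (chromosome 5, 138465479 to 138469303), rose from 1.24 ± 0.143 to 78.5 ± 48.1 CPM, a log2 fold change of 5.99 ± 0.62. Its T47D-TR counts were 1536, 2472 and 505, the last in replicate 3, without which the list had a camera adjusted p = 3.92e-28. DUSP6, which encodes an ERK phosphatase (chromosome 12, 89347235 to 89352501), rose from 2.09 ± 0.228 to 57.0 ± 9.74 CPM (log2 4.76 ± 0.16, edgeR adjusted p = 1.2e-10). The member that fell was CCND1, the cyclin D1 gene, from 248 ± 7.75 to 163 ± 9.35 CPM. EREG, the gene of the EGF-family ligand epiregulin (chromosome 4, 74365145 to 74388749), rose 51.3-fold from 4.50 ± 0.646 to 231 ± 68.7 CPM (edgeR adjusted p = 8.8e-10), and its neighbour AREG, the amphiregulin gene (chromosome 4, 74445136 to 74455005), rose 42.9-fold from 4.36 ± 0.238 to 187 ± 69.5 CPM (edgeR adjusted p = 7.6e-09). Their receptor gene EGFR went from 140 to 289 ± 41.3 CPM. Of the 28 receptor tyrosine kinases and ligands, 15 rose and 7 fell, among them the growth factor receptor gene FGFR3, from 21.8 ± 0.876 to 7.97 ± 2.09 CPM (median 0.41, camera adjusted p = 0.035, and adjusted p = 0.511 with an estimated correlation). That call ended on ranks (0.126), with limma on log2 CPM (adjusted p = 0.0784 to 0.0913) and with voom (0.0676).

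Hypoxia and glycolysis genes rose in 26 of 36 members and fell in 3, with a median of 0.71 (camera adjusted p = 3.3e-10, and adjusted p = 0.334 with an estimated correlation). CA9, a carbonic anhydrase gene induced by hypoxia (chromosome 9, 35673928 to 35681159), rose from 0.389 ± 0.0883 to 42.4 ± 11.7 CPM (log2 6.75 ± 0.28, edgeR adjusted p = 1.8e-09), with 851, 1041 and 506 counts in the T47D-TR libraries. The glucose transporter gene SLC2A3 (chromosome 12, 7919230 to 7936187) rose from 6.74 ± 0.197 to 198 ± 59.2 CPM. PFKFB3, which encodes a regulator of glycolysis, and the enolase gene ENO1 fell, with log2 fold changes of -0.76 and -0.46. In the list of ATF4 targets and amino acid response genes 19 of 28 rose and 3 fell (median 0.78, camera adjusted p = 0.000113, and adjusted p = 0.457 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, rose from 4.63 ± 0.285 to 35.0 ± 6.04 CPM and the stress-induced SESN2 from 15.7 ± 1.47 to 51.6 ± 5.44 CPM, whereas the transcription factor gene ATF5 fell from 56.4 ± 1.13 to 21.7 ± 2.21 CPM. In the unfolded protein response list 12 of 23 rose and 3 fell (median 0.18, camera adjusted p = 0.0432, and adjusted p = 0.4996 with an estimated correlation), with ERN1, the stress sensor IRE1, at a log2 fold change of 2.24 and its target XBP1 at 1.35. This call ended without T47D replicate 1 (0.0541), T47D replicate 2 (0.0504) or T47D-TR replicate 3 (0.0509), with library size alone (0.0576) and at a mean CPM of at least 5 (0.0660).

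Transcripts of the mitochondrial genome rose while nuclear genes of the respiratory chain fell. Of 13 mitochondrially encoded genes 12 rose and 1 was not called (median 0.76, camera adjusted p = 1.89e-10, and adjusted p = 0.0879 with an estimated correlation). With library size alone 11 were called higher, and 9 with voom, where quantile normalization gives the most abundant genes of each library like values and left COX1 and ATP6 just under 0 (ATP6 -0.01). Together with the mitochondrial ribosomal RNA genes RNR1 and RNR2, where these were in the table, they took 6.25% to 6.40% of the counts in T47D and 10.0% to 10.4% in T47D-TR. COX2, a cytochrome oxidase subunit gene (mitochondrial genome, 7586 to 8269), rose from 5786 ± 155 to 11796 ± 81.2 CPM (log2 1.03 ± 0.02, edgeR adjusted p = 5.9e-11), and ND6, a complex I subunit gene, by 0.92. Among 33 nuclear genes of the chain 19 fell, 3 rose and 11 were not called (median -0.21, camera adjusted p = 0.0118, and adjusted p = 0.510 with an estimated correlation). The cytochrome c gene CYCS fell from 443 ± 8.21 to 288 ± 12.3 CPM and SDHB, a succinate dehydrogenase subunit gene, from 171 ± 5.97 to 114 ± 3.63 CPM.

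Cholesterol biosynthesis genes were lower in T47D-TR. Of 25 members 21 fell and 4 were not called (median -0.88, camera adjusted p = 1.78e-09, and adjusted p = 0.334 with an estimated correlation). HMGCS1, which encodes an early enzyme of the mevalonate pathway (chromosome 5, 43287470 to 43313412), fell from 601 ± 11.1 to 105 ± 27.3 CPM (log2 -2.52 ± 0.24, edgeR adjusted p = 1.3e-08), and SQLE, the squalene epoxidase gene, from 292 ± 6.18 to 104 ± 23.1 CPM. Sterol efflux genes and other targets of the sterol-sensing receptor LXR rose in 6 of 10 members and fell in 1 (median 0.82, camera adjusted p = 0.000867, and adjusted p = 0.386 with an estimated correlation). ABCA1, a cholesterol exporter gene, rose 14.6-fold from 0.667 ± 0.09 to 9.90 ± 2.34 CPM. Heat shock genes fell in 17 of 19 members and 2 were not called (median -0.67, camera adjusted p = 9.96e-12, and adjusted p = 0.206 with an estimated correlation). The inducible chaperone genes HSPA1A (chromosome 6, 31815543 to 31817942) and HSPA1B fell from 243 ± 4.43 to 26.0 ± 11.4 CPM and from 180 ± 4.86 to 17.9 ± 8.71 CPM. They are near-identical copies, so the division of reads between them is uncertain.

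Lists of several cell states were higher in T47D-TR side by side. Among mesenchymal transition genes 16 of 23 rose and 3 fell (median 0.54, camera adjusted p = 7.39e-07, and adjusted p = 0.0879 with an estimated correlation). FN1, the fibronectin gene (chromosome 2, 215360865 to 215436068), rose from 5.19 ± 0.622 to 55.3 ± 1.45 CPM (log2 3.41 ± 0.10, edgeR adjusted p = 1.6e-11), while the receptor kinase gene AXL fell from 195 ± 2.99 to 117 ± 18.4 CPM. Extracellular matrix and protease genes rose in 21 of 29 members (22 adjusted over the list alone) and fell in 3 (median 0.72, camera adjusted p = 9.05e-07, and adjusted p = 0.206 with an estimated correlation). The tenascin gene TNC rose from 3.5 ± 0.249 to 14.4 ± 0.752 CPM and the thrombospondin gene THBS1 fell from 197 ± 6.62 to 101 ± 29.9 CPM. Basal and myoepithelial markers rose in 11 of 18 members and fell in 3 (median 0.66, camera adjusted p = 0.000213, and adjusted p = 0.206 with an estimated correlation), with ITGB4, an integrin gene of hemidesmosomes (chromosome 17, 75721459 to 75757818), at 31.2 ± 1.52 and 273 ± 25.6 CPM. Luminal identity genes rose in 10 of 16 members and fell in 2 (median 0.69, camera adjusted p = 0.000286, and adjusted p = 0.297 with an estimated correlation). KRT19, a luminal keratin gene (chromosome 17, 41523617 to 41528308), rose from 27.8 ± 1.23 to 112 ± 3.62 CPM, and KRT7, another keratin gene, fell from 584 ± 5.19 to 483 ± 40.3 CPM. Of 30 oestrogen-induced genes 17 rose, with AREG and the transcription factor gene EGR3 (3.52) highest, and 7 fell, with IL17RB, an interleukin receptor gene, lowest at -1.31. Their median was 0.38 (camera adjusted p = 0.0129, and adjusted p = 0.334 with an estimated correlation), and the call ended on ranks (0.0636) and at a mean CPM of at least 5 (0.0558). AREG is also listed among the receptor ligands, and CCND1 and MYC in the MAPK list, so these list calls are not independent. Since ESR1 was near the limit of detection in both groups, the call is not a measure of oestrogen receptor activity.

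Calcium-binding S100 and annexin genes rose in 14 of 19 members and fell in 2 (median 0.57, also with the member at 0 in T47D taken at its bound; camera adjusted p = 0.000107, and adjusted p = 0.334 with an estimated correlation). Mucins and secretory products rose in 5 of 6 members (median 1.60, camera adjusted p = 0.000213, and adjusted p = 0.202 with an estimated correlation), among them the gel-forming mucin gene MUC5B, from 3.43 ± 0.498 to 15.1 ± 3.26 CPM. The mucin list was fixed with 25 members, of which 10 were in the table, so these 6 are a small part of it. At a mean CPM of at least 5 too few of them were left for camera. Markers of other cell types went both ways beside these lists. Of 6 tested fibroblast markers 3 rose and 2 fell (camera adjusted p = 0.432), with the proteoglycan gene LUM falling from 13.9 ± 1.8 to 0.253 ± 0.0873 CPM and the matrix gene FBLN1 rising from 96.6 ± 2.69 to 269 ± 24.9 CPM. The median of that list was 0.43, its mean was -0.47 and its test pointed up. Its members MMP2, THY1, S100A4 and PDGFRB also stand in other lists. Of 4 immune and endothelial markers, too few for camera, 2 rose and 1 fell. Camera could test 5 members and called them higher without T47D replicate 2 (adjusted p = 0.0367) or T47D-TR replicate 1 (0.0107), 2 (0.0237) or 3 (0.0347), and tested 8 with no filter, without a call (0.0815). The endothelial adhesion gene PECAM1 (chromosome 17, 64319415 to 64390860) rose from 0.669 ± 0.0287 to 27.3 ± 3.81 CPM, the macrophage marker CD68 had a log2 fold change of 1.44, and the T cell marker CD8A one of -1.33.

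Cell cycle genes were slightly lower and cell cycle inhibitors higher in T47D-TR. Of 40 cell cycle genes 25 fell and 5 rose (25 and 6 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.000213, and adjusted p = 0.255 with an estimated correlation). AURKB, a mitotic kinase gene, fell from 83.6 ± 1.39 to 46.1 ± 1.06 CPM and the phosphatase gene CDC25A from 84.9 ± 1.14 to 45.9 ± 4.23 CPM. Of 16 inhibitors 9 rose and 3 fell (median 0.28, camera adjusted p = 0.00677, and adjusted p = 0.334 with an estimated correlation). This call ended on ranks (0.0775) and with limma on log2 CPM (adjusted p = 0.0538 to 0.0555). CDKN2B, which encodes the inhibitor p15 (chromosome 9, 22002903 to 22009313), rose from 30.1 ± 1.21 to 230 ± 27.4 CPM (log2 2.93 ± 0.10, edgeR adjusted p = 3.8e-11). It overlaps an antisense gene, and without a stated strand setting the reads of the pair cannot be told apart. CDKN1A, the p21 gene, rose from 14.8 ± 1.42 to 60.03 ± 7.54 CPM, and CDKN2C, the p18 gene, fell from 38.0 ± 2.01 to 18.2 ± 0.933 CPM. Lysosome and autophagy genes rose in 25 of 38 members and fell in 9 (median 0.33, camera adjusted p = 0.000409, and adjusted p = 0.334 with an estimated correlation). The autophagy kinase gene ULK1 rose from 41.9 ± 3.17 to 121 ± 13.2 CPM and the autophagy receptor gene SQSTM1 fell from 903 ± 18.8 to 583 ± 104 CPM.

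**Figure D2:**
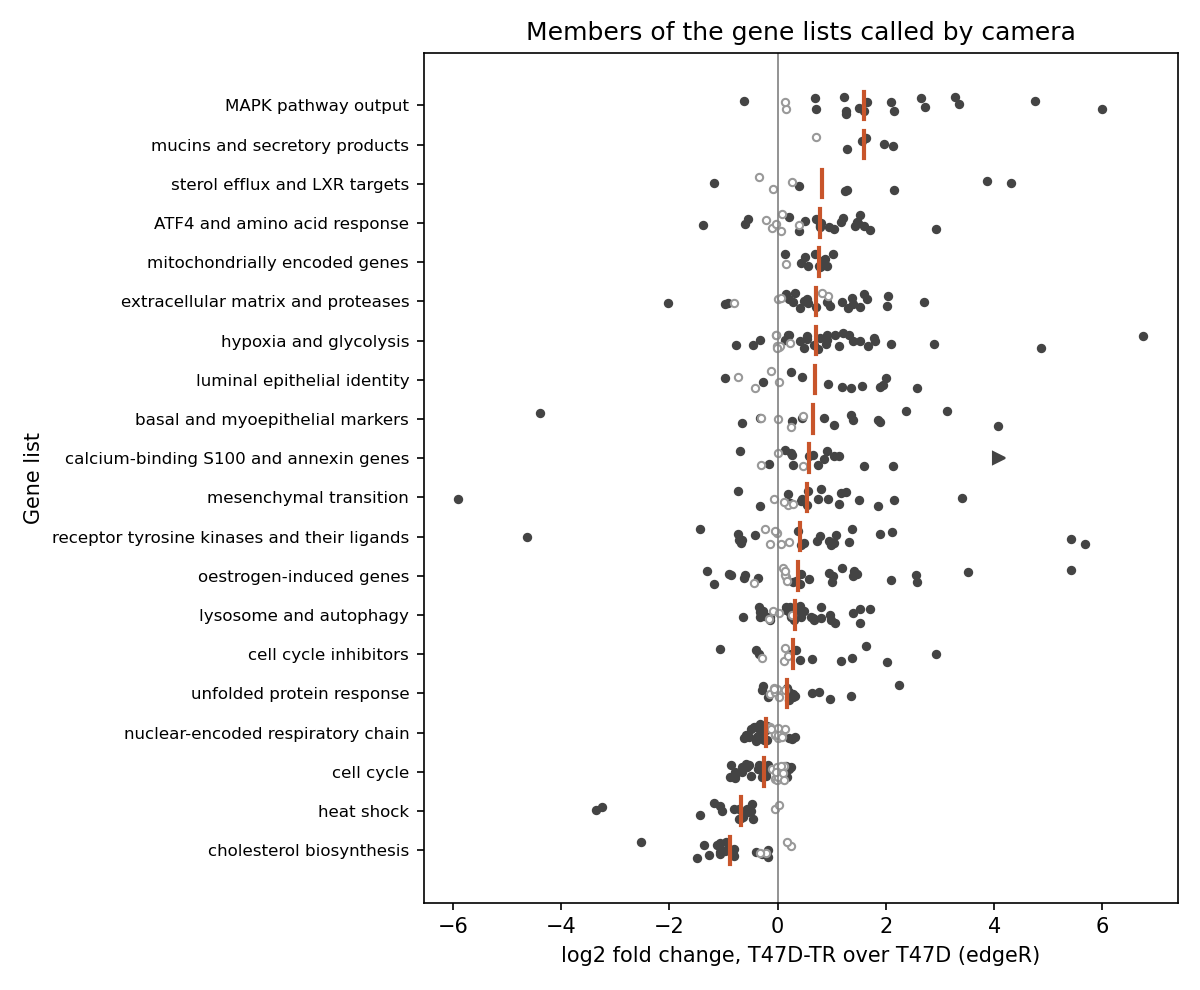
log2 fold changes (edgeR, T47D-TR over T47D) of the tested members of the 20 lists called by camera, with filled points for called members, open circles for members not called, orange bars for list medians and a triangle at the lower bound of S100A9. MAPK pathway output has a median of 1.60, and cholesterol biosynthesis and heat shock have medians of -0.88 and -0.67.

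The other lists were not called by camera. Closest to the threshold were NRF2 targets (8 rose and 13 fell of 24, adjusted p = 0.0529), fatty acid oxidation (14 and 3 of 19, adjusted p = 0.066), the TGF-beta and BMP pathway (15 and 7 of 25, adjusted p = 0.0774) and epithelial adhesion (11 and 5 of 18, adjusted p = 0.0925). Without T47D-TR replicate 3 camera called NRF2 targets (adjusted p = 0.0347), the TGF-beta and BMP pathway (0.0202), apoptosis regulators (0.0289), androgen, progestin and glucocorticoid targets (0.00169) and drug metabolism and efflux (0.00575). NRF2 targets were also called without T47D replicate 1 (0.0464) or T47D replicate 3 (0.0488), and fatty acid oxidation without T47D-TR replicate 1 (0.0331). With all libraries, apoptosis regulators had 16 members that rose and 5 that fell of 27 (16 and 6 adjusted over the list alone; camera adjusted p = 0.156), androgen, progestin and glucocorticoid targets 9 and 4 of 16 (0.187), and drug metabolism and efflux 16 and 8 of 28 (0.683). The Wnt pathway had 14 and 7 of 30 (camera adjusted p = 0.184), DNA repair 8 and 13 of 31 (0.296), NF-kB and inflammatory mediators 12 and 6 of 20 (0.322), interferon-stimulated genes 14 and 8 of 34 (0.439) and chromatin modifiers 10 and 8 of 32 (0.541). The Notch pathway had 7 and 7 of 16 (camera adjusted p = 0.642), MHC class I presentation 4 and 5 of 17 (0.714), stem cell associated genes 9 and 5 of 15 (0.762), steroid receptors and coregulators 9 and 7 of 22 (0.89), fatty acid and lipid synthesis 8 and 8 of 23 (0.905) and Hippo targets 6 and 8 of 21 (0.98). Replication-dependent histones, listed with the poly(A) selection in mind, had 3 and 2 of 11 (2 and 1 adjusted over the list alone; camera adjusted p = 0.98). A comparison between the groups cannot check that selection. The median level of the tested histone genes was 2.56 CPM in T47D and 2.51 CPM in T47D-TR. Of 18 reference genes 4 rose and 9 fell (camera adjusted p = 0.683), among them B2M, which rose by 0.77, and the tubulin gene TUBB, which fell by 0.44, both on the log2 scale. Of 3 tested metallothioneins, too few for camera, 1 rose and 1 fell.

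Median, mean and test differed in sign for some uncalled lists. NRF2 targets had a median of -0.28 and a mean of 0.14 and tested down, and the Notch pathway had -0.08 and 0.39 and tested up. Hippo targets had a median of 0.03 and a mean of -0.12 and tested up. Stem cell associated genes had 0.46 and -0.00, fatty acid and lipid synthesis 0.05 and 0.02, and histones 0.00 and 0.16, and these 3 lists tested down.

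Many of the genes taken for the size of their change were close to absent from one culture. CASP14, which encodes a caspase of keratinocyte differentiation (chromosome 19, 15049480 to 15058293), rose from 0.107 ± 0.0552 to 71.0 ± 2.93 CPM (log2 9.30, edgeR adjusted p = 1.1e-12). The T47D libraries held 3, 1 and 2 counts of it, so the size of this change is uncertain. HAS2, a hyaluronan synthase gene (chromosome 8, 121612116 to 121641440), was 271 times higher (95% interval 74.6 to 2242). Its T47D counts were in replicate 1, and without that library it was at least 121-fold higher. PADI3, a peptidylarginine deiminase gene, was 104 times higher (28.5 to 867). Against the floor of 3 counts over the group, the calcium-binding gene S100A9 was at least 16.97-fold higher, the protease gene CAPN8 at least 18.0-fold and the lncRNA genes LOC105378111 and LINC00330 at least 38.7-fold and 21.04-fold. In the other direction, RAPGEF5, which encodes a guanine nucleotide exchange factor (chromosome 7, 22118236 to 22357154), was at least 92.0-fold lower, the homeobox gene HOXD13 at least 48.1-fold, NPFFR2, a neuropeptide receptor gene, at least 46.8-fold and PDCD1, the PD-1 gene, at least 25.2-fold. RNF212, a meiotic ligase gene (chromosome 4, 1056251 to 1113710), was 648 times lower (95% interval 179 to 5355), and without T47D-TR replicate 3, which held its T47D-TR counts, at least 301-fold lower.

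The authors' deposited table listed 9108 genes at a false discovery rate under 0.05, with 4749 higher and 4359 lower, and 1832 and 694 of at least 2-fold. There were 241 genes in the authors' deposited table that stood at a log2 fold change of 20 in size because one group was at 0. Among tested genes, 8728 were called with the same sign by edgeR and in the authors' deposited table, 0 with opposite signs, 1325 by edgeR alone and 5 in the authors' deposited table alone. The signs were the same for 99.4% of tested genes, and 375 further calls of the authors' deposited table concerned genes that were not tested here.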

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

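Limma on log2 CPM, the filter at a mean CPM of 5, voom and the fit without mitochondrial genes were tests chosen after the result was seen, and the others were planned. No called gene was called in the opposite direction in any setting that tested genes. A change of sign without a call was not counted, and with voom 2 of the mitochondrially encoded genes lay below 0. Leaving out libraries gave 4669 to 5434 genes higher and 4378 to 5231 lower, with 1610 to 1713 and 639 to 736 at least 2-fold. DESeq2 gave 4656 and 4407 (1 adjusted p missing), library size alone 4827 and 5298, median-of-ratios factors 5150 and 4918, no filter 5503 and 5011, no trend 5206 and 4877, a robust fit 5188 and 4906, voom 4361 and 5789, and the fit without mitochondrial genes 5124 and 4962. Of 174 named tested genes 10 lost a call in some alternative and 7 when a library was left out. Symbols did not repeat, so keeping entries apart was not run, and the planned FPKM pseudocounts and filters were run on CPM. Depth limits the genes near 3 counts. Small changes may have been missed too, at a rate that the 48% recovery of the smallest simulated changes does not measure. The simulation gave 155 calls, against 10053 here, and used the same dispersion for all genes. Except where fewer genes or libraries are named, the cause was not tested for any change given here.

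At least 2-fold, limma on log2(CPM + 1) gave 1022 higher and 275 lower, where the added pseudocount shrinks the changes of low genes, and a mean CPM of at least 5, which tests 11342 genes, gave 801 and 170. The lowest within-group correlation, 0.990, was 0.994 with log2(CPM + 1), 0.988 with log2(CPM + 0.01), 0.988 with no filter, and 0.990 to 0.994 without each library.

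The fit with the replicate number as a block gave 5127 genes higher and 4827 lower, 1613 and 623 of them at least 2-fold, and changed no list call. Deviations from the group means correlated at -0.00512, -0.0208 and -0.0138 between libraries of the same number, not every library correlated best with its own number, and so the numbers do not pair the samples.

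With an estimated correlation camera called 0 lists higher and 0 lower (7 lists at an unadjusted p under 0.05), where fry called 28 higher and 5 lower. Adjusted p with an estimated correlation was 0.0879 for mesenchymal transition and for mitochondrially encoded genes, 0.202 for mucins, 0.206 for basal markers, extracellular matrix and heat shock, 0.255 for cell cycle, 0.297 for luminal identity and 0.386 for LXR targets. It was 0.334 for oestrogen-induced genes, MAPK output, cell cycle inhibitors, cholesterol biosynthesis, hypoxia, lysosome, and S100 and annexin genes. It was 0.457 for ATF4, 0.4996 for the unfolded protein response, 0.510 for the nuclear respiratory chain and 0.511 for receptor tyrosine kinases.

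Fry also called epithelial adhesion (adjusted p = 0.00056), DNA repair (0.000594), androgen targets (0.0012), Wnt (0.00126), fibroblast markers (0.00187), fatty acid oxidation (0.00203), interferon-stimulated genes and the TGF-beta pathway (0.00247 each), apoptosis (0.00421), NF-kB (0.00709), chromatin modifiers (0.0293), Notch (0.0296) and steroid receptors (0.0464). It tests whether a list moves one way, not against other genes.

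On ranks, calls ended for oestrogen-induced genes (adjusted p = 0.0636), receptor tyrosine kinases (0.126) and cell cycle inhibitors (0.0775), and fatty acid oxidation was called (0.0201). At a mean CPM of at least 5 the calls of oestrogen-induced genes (0.0558) and the unfolded protein response (0.0660) ended and mucins had too few members for a test, and the call of the unfolded protein response ended also with library size alone (0.0576). With limma on log2(CPM + 0.01), log2(CPM + 0.1) and log2(CPM + 1), receptor tyrosine kinases were at 0.0784, 0.0861 and 0.0913, cell cycle inhibitors at 0.0540, 0.0538 and 0.0555, and fatty acid oxidation at 0.0151, 0.0159 and 0.0162. With voom, receptor tyrosine kinases were at 0.0676 and fatty acid oxidation at 0.01003. With no filter, fatty acid oxidation (0.0321), NRF2 targets (0.0351) and the TGF-beta pathway (0.0322) were called, and NRF2 targets also with library size alone (0.0439) and median-of-ratios factors (0.0487).

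Lists called in no setting but reversed in some were the following. Fatty acid synthesis reversed on ranks (adjusted p = 0.821), with fry (0.501), limma at those pseudocounts in order (0.817, 0.827, 0.825) and voom (0.698). Hippo targets reversed on ranks (0.645), with library size alone (0.994) and limma (0.797, 0.790, 0.751). Stem cell genes reversed on ranks (0.312), with limma (0.369, 0.369, 0.379) and voom (0.272). Histones reversed on ranks (0.948), with fry (0.615), library size alone (0.994), limma (0.957, 0.960, 0.966), a mean CPM of at least 5 (0.965) and without mitochondrial genes (0.970). Leaving out a library also reversed Hippo targets (without T47D replicate 3, 0.994, T47D-TR replicate 1, 0.842, or T47D-TR replicate 2, 0.718), stem cell genes (without T47D-TR replicate 1, 0.968, or T47D-TR replicate 3, 0.554) and histones (without T47D replicate 1, 0.868, T47D replicate 3, 0.994, T47D-TR replicate 1, 0.979, or T47D-TR replicate 2, 0.923).

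Without each library in turn, adjusted p of camera ranged from 0.0331 (without T47D-TR replicate 1) to 0.110 for fatty acid oxidation, from 0.0179 to 0.0541 (T47D replicate 1) for the unfolded protein response, which also lost its call without T47D replicate 2 (0.0504) or T47D-TR replicate 3 (0.0509), and from 0.429 to 0.994 for Hippo targets, 0.554 to 0.968 for stem cell genes and 0.533 to 0.994 for histones. With the lowest value without T47D-TR replicate 3, it ranged from 0.00575 to 0.646 for drug metabolism, 0.0347 to 0.167 for NRF2 targets (called also without T47D replicate 1, 0.0464, or T47D replicate 3, 0.0488), 0.0289 to 0.191 for apoptosis, 0.00169 to 0.230 for androgen targets and 0.0202 to 0.103 for the TGF-beta pathway. Immune and endothelial markers, too few with all libraries, could be tested and were called without T47D replicate 2 (0.0367), T47D-TR replicate 1 (0.0107), T47D-TR replicate 2 (0.0237) or T47D-TR replicate 3 (0.0347), since fewer libraries let 5 members pass the filter, and with no filter 8 members were tested and not called (0.0815).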

Other observations

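The regional test was planned before its result was seen, while the tests on ESR1, the mitochondrial transcripts and the splits of the libraries were chosen after the result was seen.

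The genes of this and the next paragraph are ends of lists that camera did not call, taken by the naming rule. ID2 and ID3, which encode inhibitors of basic helix-loop-helix factors, fell from 43.0 ± 3.1 to 2.41 ± 0.437 CPM and from 257 ± 3.19 to 35.9 ± 2.28 CPM (edgeR adjusted p = 3.6e-11 and 3.3e-12), while the stem cell factor gene KLF4 rose from 14.1 ± 0.687 to 55.5 ± 7.97 CPM. SMAD9, a BMP signal transducer gene, fell from 11.4 ± 0.311 to 1.79 ± 0.255 CPM, while LTBP1, which encodes a protein that holds latent TGF-beta in the matrix, rose from 15.8 ± 0.816 to 97.2 ± 5.28 CPM. Of the BMP ligand genes, BMP2 rose from 0.601 ± 0.281 to 3.27 ± 0.317 CPM and BMP4 fell from 3.70 ± 0.403 to 0.808 ± 0.351 CPM. The Notch ligand gene JAG1 rose from 15.0 ± 1.67 to 58.0 ± 8.32 CPM and its relative JAG2 fell from 86.2 ± 3.1 to 40.02 ± 6.66 CPM. SMARCA2, a chromatin remodelling ATPase gene, rose 11.1-fold from 6.51 ± 0.55 to 72.4 ± 7.56 CPM, and its alternative SMARCA4 fell from 405 ± 3.5 to 291 ± 11.2 CPM. Among NF-kB and inflammatory genes, with a list median of 1.04 on the log2 scale, the cytokine gene IL32 fell 25.4-fold from 39.2 ± 2.11 to 1.53 ± 0.206 CPM. The interleukin gene IL1B was 89.6 times higher in T47D-TR (95% interval 15.7 to 3578), and at least 20.1-fold higher without T47D replicate 1, which held its only T47D count.

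AKR1C2, a steroid-reducing enzyme gene that is also listed as an NRF2 target, rose from 12.1 ± 1.08 to 295 ± 136 CPM, with the highest count in T47D-TR replicate 3 (7619, against 4288 and 4138), and its close paralogs leave the division of reads uncertain. AHRR, the gene of the aryl hydrocarbon receptor repressor, fell from 50.2 ± 2.6 to 4.40 ± 1.34 CPM and GSTP1, a glutathione transferase gene, from 107 ± 2.72 to 26.2 ± 3.45 CPM. Among NRF2 targets KEAP1, the gene of the NRF2 repressor, also rose, from 0.158 ± 0.0485 to 0.961 ± 0.269 CPM, while the haem oxygenase gene HMOX1 fell from 66.5 ± 1.1 to 21.1 ± 8.97 CPM and FTL, the ferritin light chain gene, from 4358 ± 12.3 to 2126 ± 260 CPM. The interferon-induced OAS1 rose from 2.74 ± 0.613 to 18.1 ± 0.339 CPM and IFIH1, the gene of the RNA sensor MDA5, fell from 4.70 ± 0.935 to 0.606 ± 0.0707 CPM. Among fatty acid oxidation genes the lipid-sensing receptor gene PPARA rose from 15.3 ± 0.288 to 38.8 ± 2.11 CPM and the isomerase gene ECI1 fell (log2 -0.56).

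ESR1 was near the limit of detection in libraries labelled as an ER-positive line and its subline. If the libraries labelled T47D stand for the parent culture, loss of ESR1 during selection for resistance is argued against as the cause. Their highest level was already 0.162 CPM. This value is part of the pattern itself and not separate evidence. Cells of another line under the labels and a loss of ESR1 alone in the parent culture cannot be told apart by the medians of the listed genes. The tested luminal and adhesion genes had a median of 13.5 CPM in the T47D libraries. They lay under the median of all tested genes in 3 of the 6 libraries, those labelled T47D. The listed members found in the deposited table, tested or not, had a median above that of all genes in it. Members missing from the table could not be counted. Of the 41 members, 11 lay under 1 CPM and 21 under 10 CPM in T47D, with GATA3 at 1.23 CPM, while KRT8 and KRT18 were high. A loss of ESR1 alone would not by itself account for low levels of other luminal genes, but their usual levels in this line are not known here. No reference profile of T47D was used here, so both explanations stay open, as does a wider loss of luminal identity in the parent culture.

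Mitochondrially encoded transcripts were higher in T47D-TR. An equal rise of mitochondrial RNA of each kind in the T47D-TR libraries is argued against as the only cause. The log2 fold changes of the 13 genes spread by 0.89 (SE 0.0606), from 0.14 in ND1 to 1.03 in COX2. The spread cannot decide on a general rise combined with differences between the genes, as 12 of the 13 were called higher. The choice of scaling is argued against as well, since the median of the 13 genes, 0.76 with TMM, was 0.72 with library size alone, 0.75 with median-of-ratios factors and 0.51 with quantile normalization, which by construction evens out the most abundant genes. A difference in the processing or stability of mitochondrial transcripts in the subline or under the drug stays open and was not tested.

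Neighbouring genes shifted together in some regions. Of 370 blocks of 40 genes, 8 had a shifted median, each upwards, against at most 3 in any of 1000 shuffled gene orders, and 95.5% of tested genes could be placed. That all were upwards depends on the threshold. Lowered blocks lay just under it, as near the start of chromosome 1 (z down to -3.84), and so did raised ones, as on chromosome 18 (z 3.95). The shifted blocks lay on chromosomes 18 (3 blocks), 20 (2 blocks), 11, 22 and X, and the median log2 fold change was 0.44 over the 213 genes of chromosome 18 and 0.21 over the 398 of chromosome 20. A copy-number difference between the cultures is a candidate explanation for these 8 blocks as a set, not for each of them. A median of 80.2% of their genes moved with the block, only just over the 80% set beforehand, against 68.3% in shuffled blocks past the threshold. The share ran from 70.5% in the block on chromosome 22, close to the shuffled value, to 90.5% in a block on chromosome 18. Shared chromatin or regulation was not tested, and since only 45.9% of simulated shifts of 0.5 were found, smaller gains or losses may have been missed.

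The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. In each of the 5 counts tested, 1 of the 10 splits, the real one, gave a result as large. The real split gave 5186 genes higher and 4867 lower, 1617 and 618 of them at least 2-fold, and the highest count in the other splits was 0 by edgeR, with 42 to 128 genes at an unadjusted p under 0.05. Camera called 20 lists in the real split and 8 to 17 in each of the others, with the preset correlation. Each other split mixes both labels on both sides in unequal shares. It therefore keeps part of the difference between the cultures, while the rest widens the spread within a side. For this reason neither the 0 genes of edgeR nor the list calls of camera in these splits give a rate of false calls.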
